A study of Mus musculus with 4 samples.

How the data were processed

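Bulk RNA-seq libraries from cultured wild-type MC38 mouse tumour cells were analysed, 2 unirradiated and 2 taken 60 h after a single 30 Gy X-ray fraction. RNA was extracted with Trizol, and 1 µg of total RNA entered each library, per the labels' protocols. Whether the kit kept strand, and how messenger RNA was selected, is not given in the sources used here. The submitters' processing notes name HISAT2, HISAT, HTSeq and DESeq2 and the mm10 build of the mouse genome, without versions, roles or order. Annotation release, strand setting and the treatment of reads that match several places are not given in the sources used here. These choices affect what a count means: reads from genes with near-identical copies, such as histones, MHC class I genes and Ifit3b, may be dropped or divided, and without strand reads of overlapping antisense genes cannot be told apart. Of the genes selected by the naming rule given below, 14 have exons that overlap another annotated gene. For 6 the other gene holds over 10% as many counts (Alas2, Dclre1c, Kif20a, Piezo1, Psmb9 and Tnfsf9). Genes named beyond that rule were not checked for overlap.

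The values deposited by the authors are whole-number counts per Ensembl gene, 1 column per library, neither normalized nor pooled. Column totals run from 26059171 to 29881492, and no gene is at 0 in every library. Groups and replicate numbers were taken from the sample titles. The description of unirradiated replicate 2 carries the replicate number of the other unirradiated sample, in conflict with its title, and the title was followed because the column name matches it. The table holds 26561 genes, 189 of which had no symbol in the gene name table used. Symbols, coordinates (GRCm38, 1-based) and exons come from GENCODE release M21, which is of the same build as mm10 but need not be the release the authors counted with.

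Differences between the groups were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, glmQLFit with robust estimation and glmQLFTest, with a term for irradiation alone. P-values were adjusted by Benjamini-Hochberg over the 15298 genes that passed the filter, which hold 99.9% of the counts, and 11263 genes were left out. A gene changed where the adjusted p was under 0.05. CPM are counts per 1e+06 counts of the TMM-scaled library size, computed from the deposited counts, and are given as mean ± SD over the 2 libraries of a group. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. The median over genes of the estimated prior degrees of freedom was infinite. A gene with an infinite value takes its spread from the fitted trend rather than from its own counts, and genes without one were not counted. P-values too small to be held as numbers are given as below 1e-300. For a gene at 0 in a whole group the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio has an exact (Clopper-Pearson) 95% interval, all of which cover counting error only. Library similarity was described by Pearson correlation of log2(CPM + 1) and replicate libraries were compared by chi-square over genes with at least 20 counts.

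Before the data were examined, 17 lists of response genes, 2 quality lists and 7 lists of cell type markers were fixed, together with the rule for the genes named in the text and the alternatives. The rule names Piezo1 and Piezo2, the 4 genes that rose and the 4 that fell with the largest change among those past the threshold with a mean of at least 5 CPM, separated libraries and a proper gene name, the 2 most changed members of each response list at the same level, and the highest member of each other list. A gene that the rule selects is not reported here by name. Genes named beyond it are said to have been chosen after their values were seen. For each list the members higher and lower are counted over all tested genes and adjusted over the list alone. Response and quality lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg over the 19 lists. Camera was run again with the correlation estimated from the residuals, of which the design leaves only 2 degrees of freedom per gene. Its p-values then also rest on 2 degrees of freedom, and no list passed at 0.05 in that form. A further 7 lists, written after the most changed genes had been seen, are used only in the closing observations.

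The pipeline was tested on simulated data, with counts drawn from the real means and library sizes and 50 genes planted at each fold. Of 50 planted genes it recovered 22 at 1.2-fold, 39 at 1.5-fold, 46 at 2-fold and 50 at 4-fold, and it called 4 unchanged genes among 14920 tested. Camera called the planted list and 0 of 20 random lists. Planted genes had a mean of at least 1 CPM, with as many raised as lowered at each fold. They were a far smaller share of the genes than the 60.7% that changed in the data. Genes were drawn independently with the fitted dispersions. The simulation therefore cannot test scaling under so wide a change, a wrongly estimated spread or camera with correlated genes. Alternatives tried were DESeq2 size factors, upper quartile factors and library totals in place of TMM, no filter on low counts and minimum means of 1 and 5 CPM, DESeq2 1.42.0, limma-voom, a fit without robust estimation, a replicate block, leaving out each library in turn, stricter thresholds and, added later, edgeR's newer quasi-likelihood method and edgeR without a filter for Piezo2. Low-count patterns were examined with 1000 bootstrap resamples of genes. Groups of 2 libraries allow no test by regrouping samples. Reads were not analysed here, so mapping, strand and duplicates were not examined.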

Results

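Messenger RNA was sequenced from MC38 cells, a line derived from a mouse colon adenocarcinoma that the labels describe as epithelial and wild type. One group was left unirradiated. The other received a single X-ray dose of 30 Gy, and its RNA was taken 60 h later. No harvest time is given for the unirradiated cells in the sources used here. Time in culture and cell density therefore cannot be told apart from irradiation. Each group holds 2 libraries. The total counts were 27995608 and 29881492 in the unirradiated libraries and 29180110 and 26059171 in the irradiated ones. A count above 0 was found for 19413 and 19531 genes in the unirradiated libraries and for 22713 and 22663 in the irradiated ones. Nothing in the labels says whether the libraries of a group came from separate cultures. P-values therefore measure only the spread between these libraries, which may be technical. For many genes that spread came from the trend fitted over all genes rather than from the gene's own counts. A gene can therefore pass although its libraries overlap. Libraries of a group differed by more than sampling noise. Their mean chi-square per gene was 3.38 in the unirradiated and 4.73 in the irradiated group, where sampling alone gives 1, so each library was kept as a sample of its own. Over the genes that passed the filter on low counts, log2 CPM (counts scaled to library size) was correlated between libraries. Pearson r was 0.997 between the unirradiated libraries and 0.996 between the irradiated ones. It was 0.969 between unirradiated replicate 1 and irradiated replicate 1. These are correlations across genes, which are not independent replicates.

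The comparison of irradiated with unirradiated cells asks how the tumour cells' own transcripts stood 60 h after a high dose. Interferon-stimulated genes rose in 37 of 38 tested members, and lysosomal genes, which encode the enzymes and membrane proteins of that organelle, rose in 27 of 28. Genes of glycolysis and the hypoxia response fell in 15 of 22 and rose in 4. The competitive test camera, with a preset correlation between genes of 0.01, gave adjusted p = 2.85e-33, 1.29e-19 and 9.18e-05 for these lists, and adjusted p = 0.168 for each with an estimated correlation. Of 15298 genes tested with edgeR's quasi-likelihood test, 9289 (60.7%) changed at a Benjamini-Hochberg adjusted p under 0.05, 4655 of them higher and 4634 lower. Most of these changes were modest, with a median absolute log2 fold change of 0.54. Fitted changes of at least 2-fold were found for 1893 genes that rose and 531 that fell, where the fitted fold of a gene at 0 in a whole group depends on the prior count. Direction varied with expression level. Of 2426 genes with a mean under 1 CPM, 724 rose and 90 fell, whereas of 2485 genes over 100 CPM, 805 rose and 1239 fell. Genes with a mean under 0.5 CPM, summed as a set, had 1.90 times as many CPM in the irradiated libraries (95% bootstrap interval over genes 1.84 to 1.94). The spread between replicates was low (biological coefficient of variation 4.57%), which lets small shifts pass the test.

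**Figure D1:**
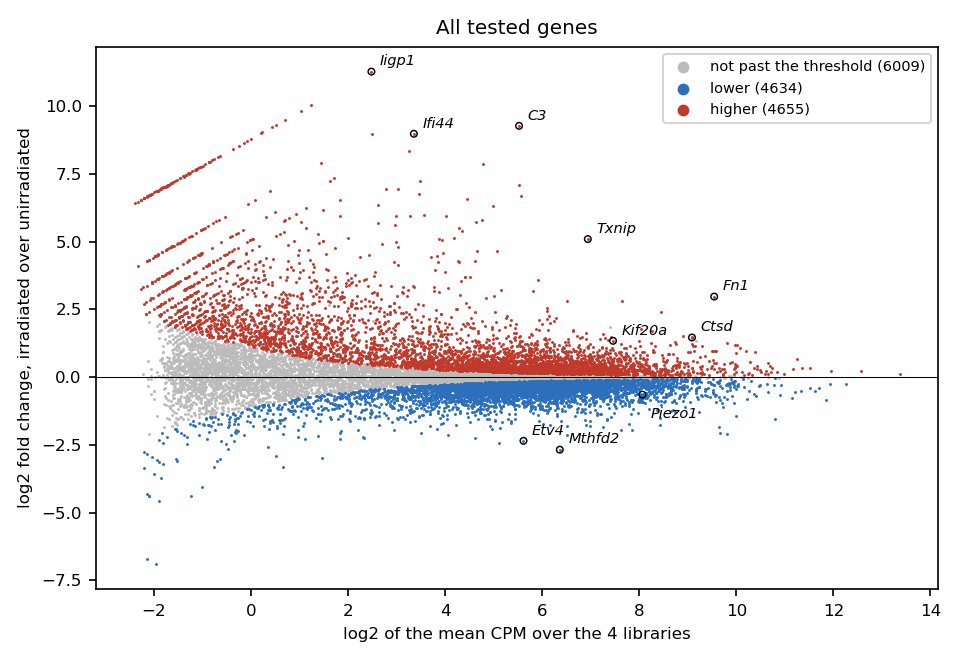
Log2 fold change of each tested gene (irradiated over unirradiated, edgeR) against the log2 of its mean CPM over the 4 libraries. CPM on this axis are per library total, without TMM factors. Genes that rose are in red (4655), genes that fell in blue (4634) and the others in grey (6009). Iigp1, C3 and Ifi44 lie highest among the labelled genes, Mthfd2 and Etv4 lowest, and the called points of low CPM are mostly above 0. Streaks at the upper left are genes with few or no counts in unirradiated cells, whose fitted folds depend on the prior count. Fn1 and Txnip were labelled after their values were seen.

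The steepest rises were in genes almost silent in unirradiated cells. Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, GRCm38), an interferon-inducible GTPase, had 0 counts in both unirradiated libraries and 319 and 298 in the irradiated ones, at least 207-fold higher when 3 counts over the unirradiated group are taken as the floor (edgeR adjusted p = 1.70e-83). C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), the central complement component, went from 0.139 ± 0.0939 to 90.2 ± 4.61 CPM (SD, n = 2 in each group), a log2 fold change of 9.27 (SE 0.16, edgeR adjusted p below 1e-300). Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960) had 0 and 2 counts before and 572 and 556 after irradiation, a ratio of 568 with an exact 95% counting interval of 157 to 4693. For Ifit3b (ENSMUSG00000062488, chromosome 19, 34607970 to 34613401) the counts were 1 and 0 against 265 and 354, a ratio of 623 (111 to 24644). Reads of Ifit3b may be shared with its close copy Ifit3, so its own level is uncertain.

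Among the genes that fell, Mthfd2 (ENSMUSG00000005667, chromosome 6, 83305691 to 83325908), a mitochondrial enzyme of folate metabolism, was 6.41-fold lower, from 145 ± 0.799 to 22.6 ± 0.221 CPM (SD, n = 2), with a log2 fold change of -2.68 (SE 0.06, edgeR adjusted p below 1e-300). Qrfp (ENSMUSG00000043102, chromosome 2, 31806166 to 31810580), a neuropeptide precursor, was 5.33-fold lower (58.9 ± 6.04 to 11.1 ± 1.58 CPM, adjusted p = 4.64e-152). Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371), an ETS-family transcription factor, was 5.11-fold lower (83.2 ± 3.58 to 16.3 ± 0.0873 CPM, adjusted p = 1.96e-212). Nppb (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205), which encodes the precursor of B-type natriuretic peptide, was 4.71-fold lower (41.3 ± 4.09 to 8.75 ± 0.222 CPM, adjusted p = 2.83e-96).

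Piezo2, a mechanically gated cation channel that the series title ties to radioresistance of tumour cells, was barely detected in either group, whereas its relative Piezo1 was abundant and fell. Piezo2 (ENSMUSG00000041482, chromosome 18, 63010213 to 63387183, minus strand) had 0 and 2 counts in the unirradiated libraries and 7 and 12 in the irradiated ones, or 0.0343 ± 0.0484 and 0.344 ± 0.153 CPM (SD, n = 2). Both irradiated libraries lay above both unirradiated ones. The ratio of counts was 9.56, with an exact 95% interval of 2.31 to 84.6 that covers counting error only. Piezo2 lay below the filter on low counts and was therefore not tested. Without that filter edgeR gave adjusted p = 0.101 and DESeq2 gave 0.102, and leaving out unirradiated replicate 2 brought it into the test at adjusted p = 0.047, leaving out unirradiated replicate 1 at 0.22, so no change of Piezo2 is established at this depth. Of 1953 genes with 15 to 30 counts in all, 374 had at least as high a share of them in the irradiated libraries. Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329, minus strand) fell 1.56-fold, from 328 ± 3.69 to 210 ± 8.01 CPM (SD, n = 2), with a log2 fold change of -0.65 (SE 0.04, edgeR adjusted p = 2.12e-73). Its exons overlap Ctu2 on the other strand.

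Of the 16 tested genes in a list of mechanosensitive and related channels, 9 fell, 4 rose and 3 did not pass the test. Adjusted over the list alone, 10 fell and 4 rose. Asic1, an acid-sensing channel, fell (log2 fold change -0.70, SE 0.15, adjusted p = 1.02e-05), and Trpm4, a calcium-activated cation channel, rose (0.70, SE 0.14, adjusted p = 1.17e-06). As a list the channels did not stand apart from other genes (median -0.28, camera adjusted p = 0.197). Their median turned to 0.43 when genes of any count entered.

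**Figure D2:**
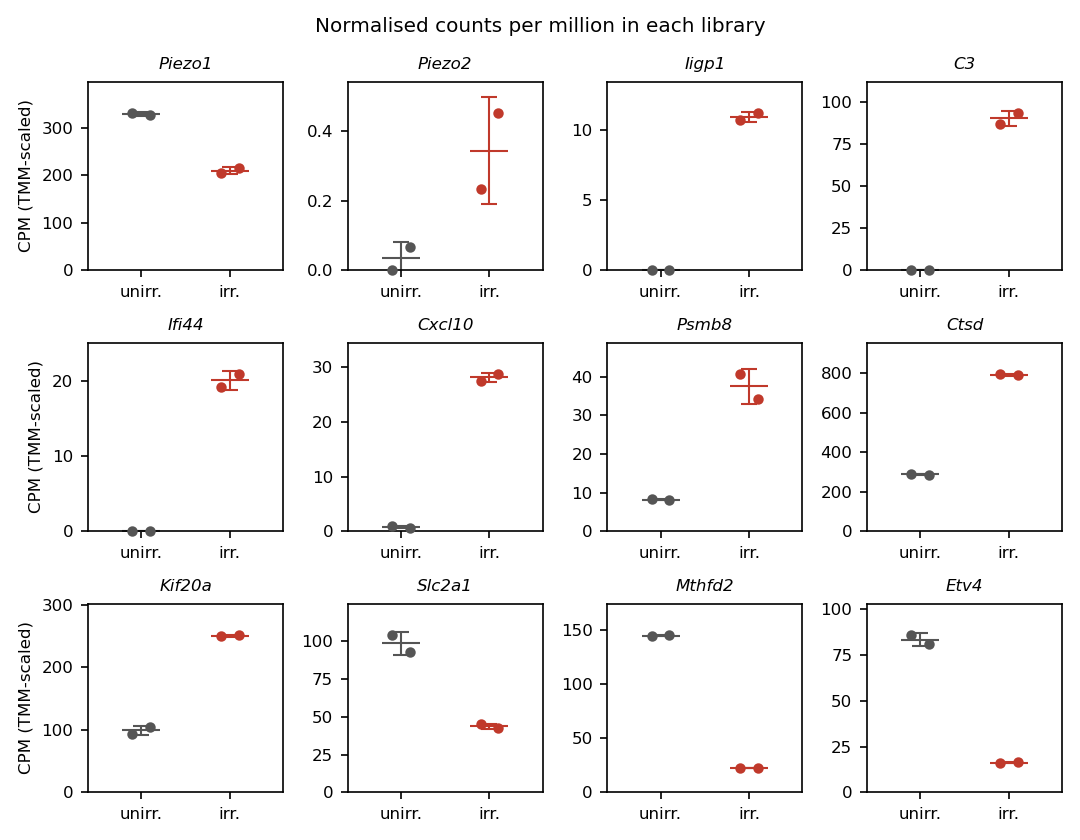
TMM-scaled CPM of 12 genes in each library, with dots for the libraries, a horizontal line for the group mean and bars for 1 SD (n = 2 per group); each panel has its own linear axis from 0. Piezo1 falls from 328 to 210 CPM, while Piezo2 stays under 1 CPM in every library.

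Of the 19 response and quality lists, the interferon-stimulated genes had the largest median shift. The 38 tested members had a median log2 fold change of 3.73, or 13.3-fold, and 37 rose while none fell (camera adjusted p = 2.85e-33, and adjusted p = 0.168 with an estimated correlation). Adjusted over the list alone, 37 rose. Beyond Ifi44 and Ifit3b, examples chosen after their values were seen are Isg15, a ubiquitin-like modifier (log2 fold change 4.24), Irf7, an interferon regulatory factor (3.86), and Mx1, an antiviral GTPase (5.96). The member that did not pass was Isg20 (0.02, adjusted p = 0.931). Transcripts of interferon beta itself were rare. Ifnb1, also chosen after its values were seen, had 0 counts in both unirradiated libraries and 17 and 8 in the irradiated ones, at least 8.39-fold higher against the floor of 3 counts over the group. It was below the filter and not tested.

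Genes of nucleic acid sensing, a list that holds sensors, adaptors, kinases and enzymes that edit or degrade nucleic acids and their precursors, rose in 10 of 17 tested members and fell in 3, with 11 and 3 when adjusted over the list alone. The list's median log2 fold change was 0.48 (camera adjusted p = 4.53e-04, and adjusted p = 0.180 with an estimated correlation). Zbp1, which binds Z-form nucleic acid, rose from 0.104 ± 0.0954 to 13.4 ± 1.09 CPM (SD, n = 2), a log2 fold change of 6.93 (SE 0.34, adjusted p = 1.86e-91). Ddx58, which encodes the RNA sensor RIG-I, rose 5.83-fold (log2 fold change 2.54, SE 0.06, adjusted p below 1e-300). Both are also in the interferon list. The members that fell were Rnaseh2a, Rnaseh2b and Rnaseh2c, the subunits of ribonuclease H2, with log2 fold changes of -0.23, -0.32 and -0.30. Tmem173, the adaptor STING, rose (0.80, adjusted p = 1.27e-09), while Cgas, the DNA sensor upstream of it, had a log2 fold change of 0.42 that did not pass (adjusted p = 0.0507). The ribonuclease H2 subunits, Tmem173 and Cgas were chosen after their values were seen.

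MHC class I presentation genes rose in 15 of 17 tested members and none fell, also when adjusted over the list alone. Their median log2 fold change was 1.27, or 2.41-fold (camera adjusted p = 9.58e-11, and adjusted p = 0.168 with an estimated correlation). The immunoproteasome subunits Psmb9 and Psmb8 rose most among members of at least 5 CPM, Psmb9 from 1.90 ± 0.318 to 10.4 ± 2.20 CPM (log2 fold change 2.44, SE 0.22, adjusted p = 3.58e-28) and Psmb8 from 8.24 ± 0.0279 to 37.5 ± 4.52 CPM (2.19, SE 0.11, adjusted p = 8.30e-86; SD, n = 2). Psmb9 overlaps Tap1 on the other strand. Chosen after their values were seen, B2m, the class I light chain, rose with a log2 fold change of 1.27, and the heavy chain gene H2-K1 with 1.13. The heavy chain gene H2-D1 rose from 16978 and 17253 to 41171 and 36935 counts. The heavy chain genes are close copies of each other, so how reads divide among them is uncertain.

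A list of T cell and natural killer cell ligands also holds genes with other roles, such as Cd47 and the ectoenzyme gene Nt5e. It rose in 10 of 15 tested members and fell in 1, Raet1e, with the same counts adjusted over the list alone. The median log2 fold change was 0.71 (camera adjusted p = 0.009, and adjusted p = 0.180 with an estimated correlation). Tnfsf9, the ligand of the costimulatory receptor 4-1BB, rose 2.14-fold (log2 fold change 1.10, SE 0.14, adjusted p = 1.46e-13), and Lgals9, a galectin, rose 1.68-fold (0.75, SE 0.05, adjusted p = 1.64e-43). Cd274, which encodes PD-L1, rose with a log2 fold change of 1.51 (adjusted p = 4.20e-09), and Cd47 with 0.71. These last examples, Nt5e and Raet1e were chosen after their values were seen. The annotated span of Raet1e covers that of Raet1d on the same strand, so the level of Raet1e alone is uncertain.

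**Figure D3:**
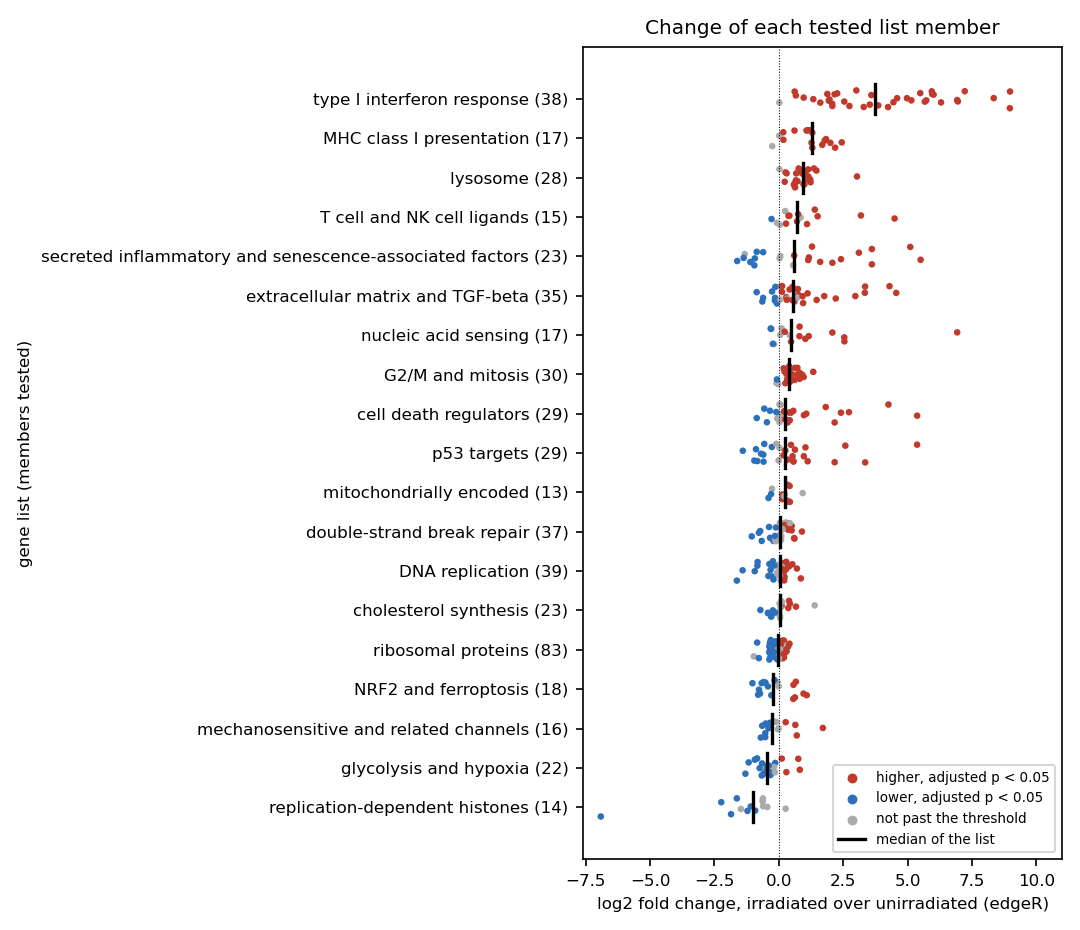
Log2 fold change (irradiated over unirradiated, edgeR) of each tested member of 19 gene lists, 1 dot per gene, red where it rose, blue where it fell and grey where it did not pass the test; black bars mark medians and numbers in parentheses give the members tested. The interferon list has the highest median (13.3-fold) and the replication-dependent histones the lowest (0.499-fold).

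Genes of G2/M and mitosis rose in 26 of 30 members and fell in 1, with the same counts adjusted over the list alone. The rise was small at the median (log2 fold change 0.41, or 1.33-fold; camera adjusted p = 3.69e-10, and adjusted p = 0.180 with an estimated correlation). Kif20a, a mitotic kinesin, rose 2.53-fold, with 2582 and 3039 counts before and 7430 and 6680 after irradiation (log2 fold change 1.34, SE 0.04, adjusted p = 2.88e-223), although its exons overlap Cdc23 on the other strand. Aurka, a mitotic kinase, rose 1.95-fold (log2 fold change 0.97, SE 0.05, adjusted p = 8.13e-81). Mki67, a proliferation marker and the member that fell, was chosen after its values were seen (-0.07, adjusted p = 4.03e-03).

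Replication-dependent histone genes fell in 7 of 14 tested members and none rose. Adjusted over the list alone, 6 fell. The median change was 0.499-fold (camera adjusted p = 0.009, adjusted p = 0.180 with an estimated correlation, and 0.057 without irradiated replicate 2). Hist1h1c, a linker histone, fell 3.10-fold (log2 fold change -1.63, SE 0.08, adjusted p = 5.50e-93) and Hist1h4i fell 4.71-fold (-2.24, SE 0.23, adjusted p = 6.03e-21). Histone H4 copies are nearly identical, so the level of Hist1h4i alone is uncertain, and most such messages lack the poly(A) tail on which many messenger RNA kits rely.

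DNA replication genes went both ways, with 15 of 39 higher and 12 lower, also when adjusted over the list alone. The list's median log2 fold change was 0.04, its mean -0.08 and the camera direction down (adjusted p = 0.757). Ccne1, which encodes cyclin E1, fell 3.09-fold (log2 fold change -1.63, SE 0.16, adjusted p = 1.97e-24), and Tk1, the thymidine kinase of S phase, fell 2.65-fold (-1.41, SE 0.05, adjusted p = 1.63e-204). Double-strand break repair was also divided, with 10 of 37 genes higher and 10 lower under both adjustments (median 0.05, camera adjusted p = 0.558). Dclre1c, the nuclease Artemis, rose (log2 fold change 0.90, SE 0.12, adjusted p = 1.15e-13), but its exons overlap Suv39h2 on the other strand. Rif1, which limits the resection of broken ends, fell (-1.05, SE 0.05, adjusted p = 4.20e-107).

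Targets of p53 did not move together, with 15 of 29 tested genes higher and 9 lower under both adjustments. The median log2 fold change was 0.24 (camera adjusted p = 0.217). Trp53inp1, a stress-induced regulator of autophagy and cell death, rose 10.2-fold (log2 fold change 3.36, SE 0.19, adjusted p = 1.53e-71), and Pmaip1, which encodes the death protein NOXA, rose 4.50-fold (2.17, SE 0.14, adjusted p = 1.57e-51). Several canonical targets shifted less or not detectably. Chosen after their values were seen, Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 0.18 (adjusted p = 1.22e-03), and Mdm2 and Ccng1 did not pass (adjusted p = 0.978 and 0.989). Phlda3 and Bax fell, with log2 fold changes of -0.69 and -0.57, and were likewise chosen after their values were seen.

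Cell death regulators rose in 16 of 29 tested members and fell in 5 under both adjustments, with a median log2 fold change of 0.24 (camera adjusted p = 0.009, and adjusted p = 0.180 with an estimated correlation). The pro-apoptotic BH3-only genes Bmf and Bcl2l11 rose 6.61-fold and 5.32-fold (log2 fold changes 2.72, SE 0.20, adjusted p = 1.29e-40, and 2.41, SE 0.11, adjusted p = 8.88e-106). Members that fell include the anti-apoptotic gene Bcl2l1 (-0.86) as well as the effectors Bax (-0.57) and Mlkl (-0.46). Fas, a death receptor, went from 2 counts in each unirradiated library to 108 and 68. Birc2 and Birc3, inhibitors of apoptosis, rose with log2 fold changes of 1.07 and 0.98. These, Bcl2l1 and Mlkl were chosen after their values were seen.

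Secreted inflammatory and senescence-associated factors rose in 12 of 23 tested members and fell in 7, or 12 and 8 when adjusted over the list alone. Cxcl10, a chemokine for activated T cells, rose 34.4-fold from 0.816 ± 0.185 to 28.1 ± 0.893 CPM (SD, n = 2; SE of the log2 fold change 0.19, adjusted p = 1.06e-160). Icam1, an adhesion molecule listed for its shed form, rose 12.2-fold (log2 fold change 3.61, SE 0.27, adjusted p = 1.49e-40). Timp1, a metalloproteinase inhibitor (-1.62), and Vegfa, an angiogenic factor (-0.93), fell and were chosen after their values were seen. The list's median was 0.60, and camera gave adjusted p = 0.0811, which passed at 0.0362 with the replicate number as a block and at 0.0370 to 0.0491 when any library was left out. With an estimated correlation the adjusted p was 0.275.

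Extracellular matrix and TGF-beta genes rose in 23 of 35 tested members and fell in 8 under both adjustments (median log2 fold change 0.53, camera adjusted p = 4.09e-05, and adjusted p = 0.168 with an estimated correlation). Dcn, the proteoglycan decorin, rose 19.7-fold from 1.83 ± 0.221 to 36.2 ± 0.217 CPM, and Thbs1, thrombospondin 1, rose 10.2-fold from 1.30 ± 0.330 to 13.2 ± 1.07 CPM (SD, n = 2; adjusted p = 1.52e-182 and 1.49e-51). Fn1, fibronectin, rose from 4679 and 4744 counts to 38598 and 34906 (log2 fold change 2.97). Ccn1, which encodes a matricellular protein, fell with a log2 fold change of -0.86. Fn1 and Ccn1 were chosen after their values were seen.

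Lysosomal genes rose in 27 of 28 tested members, also when adjusted over the list alone, with a median log2 fold change of 0.94, or 1.92-fold (camera adjusted p = 1.29e-19, and adjusted p = 0.168 with an estimated correlation). Cd68, a lysosomal membrane glycoprotein, rose 8.21-fold from 4.23 ± 0.555 to 34.6 ± 4.23 CPM, and Ctsd, the protease cathepsin D, rose 2.75-fold from 287 ± 0.407 to 791 ± 5.23 CPM (SD, n = 2; adjusted p = 7.46e-122 and below 1e-300). Gusb did not pass (0.02, chosen after its values were seen).

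Glycolysis and hypoxia genes had a median log2 fold change of -0.45, or 0.732-fold, with 15 of 22 lower and 4 higher under both adjustments (camera adjusted p = 9.18e-05, and adjusted p = 0.168 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell 2.46-fold (log2 fold change -1.30, SE 0.21, adjusted p = 2.40e-09). Slc2a1, the glucose transporter GLUT1, fell 2.25-fold from 98.4 ± 7.80 to 43.6 ± 1.72 CPM (SD, n = 2; adjusted p = 5.38e-88). Ldha, lactate dehydrogenase A (-0.84), fell, whereas Car9 (0.82) and Ndrg1 (0.76), both known hypoxia targets, rose. The last 3 examples were chosen after their values were seen.

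Antioxidant, iron and ferroptosis genes went both ways, with 6 of 18 higher and 10 lower under both adjustments (median -0.23, camera adjusted p = 0.504). Fth1, the ferritin heavy chain, rose 2.12-fold (log2 fold change 1.08, SE 0.02, adjusted p below 1e-300), and Chac1, a glutathione-degrading enzyme, fell 2.03-fold (-1.02, SE 0.10, adjusted p = 1.38e-25). Cholesterol synthesis genes were higher in 5 of 23 and lower in 8 under both adjustments, with a median of 0.03 and a mean of 0.04 against a camera direction of down (adjusted p = 0.847). Insig1, an inhibitor of the synthesis pathway, rose 1.59-fold (log2 fold change 0.67, SE 0.04, adjusted p = 2.14e-61).

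Ribosomal protein genes, read as a control of library quality, fell in 35 of 83 tested members and rose in 19 under both adjustments, with Rplp0 higher by a log2 fold change of 0.30 (SE 0.02, adjusted p = 4.41e-51). Their median of -0.04 (camera adjusted p = 0.150) turned to 0.03 with upper quartile scaling, 0.02 with library totals and 0.02 when genes under a mean of 5 CPM were left out. Mitochondrially encoded genes rose in 7 of 13 and fell in 2 under both adjustments (median 0.24, camera adjusted p = 0.197), with mt-Co1 higher by 0.13 (SE 0.01, adjusted p = 3.28e-19).

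Markers of other cell types were mostly at or near 0. No neutrophil marker could be tested, and the highest, S100a9, had 0 counts in 3 libraries and 7 in irradiated replicate 2. Of the T and natural killer cell markers 2 were tested and neither passed, Il2rb with a log2 fold change of 0.89 (SE 0.64, adjusted p = 0.223). The erythroid marker Alas2 did not pass either (0.44, SE 0.62, adjusted p = 0.563), and its exons overlap Apex2 on the other strand. All 4 tested macrophage and dendritic cell markers rose: Cd68, which is also in the lysosome list, Cd74, Lyz2 and H2-Ab1. Cd74, the invariant chain of MHC class II, went from 5 and 9 counts to 496 and 372. Lyz2 had 0 and 2 counts against 23 and 20. Endothelial markers rose in 3 of 4 tested genes, Vwf from 59 and 35 to 293 and 273 counts (log2 fold change 2.59, SE 0.23, adjusted p = 1.27e-29). Near-silent protein-coding genes as a whole, with a mean under 0.5 CPM, had 2.97 times as many CPM after irradiation. The 95% bootstrap interval over genes was 2.83 to 3.11, which leaves out the spread between libraries.

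Fibroblast markers rose in all 8 tested genes, but several were abundant before irradiation. Col1a2, a collagen chain, was at 749 ± 5.23 CPM in unirradiated and 914 ± 12.3 CPM in irradiated cells (SD, n = 2; log2 fold change 0.29, adjusted p = 1.21e-28). Of the 8, 5 are also in the matrix list: Col1a1, Col1a2, Col3a1, Dcn and Postn. Intestinal epithelial markers were sparse. Of 12 genes 5 were tested, 3 rose and none fell, with Cdh1, E-cadherin, 1.99-fold higher (35.4 ± 1.24 to 70.4 ± 3.72 CPM, SD, n = 2; adjusted p = 2.38e-48). Epcam had 0 counts in 3 libraries and 1 in irradiated replicate 2, and Vil1 had between 1 and 5 in each library. The markers other than those named first for each cell type were chosen after their values were seen.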

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

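Of the alternatives below, edgeR's newer quasi-likelihood method and edgeR without a filter for Piezo2 were chosen after the data had been seen. The number of changed genes was 9289. It lay between 8133 and 8696 when a library was left out, and was 9403 with the newer method, 8690 with DESeq2, 9287 with limma-voom, 8060 at an adjusted p under 0.01 and 7434 when genes under a mean of 5 CPM were not tested. No gene called both there and under an alternative changed direction. Requiring at least a 2-fold change brought the count to 2424, with 1893 higher and 531 lower, so that 78.1% of the changed genes were higher. The cause of that asymmetry was not tested. Without that requirement the share was 57.3% with upper quartile scaling and 56.1% with library totals, against 50.1% with TMM. The titles do not say whether the replicate numbers pair the libraries. Same-numbered libraries deviated with a correlation of -0.01 over 12872 genes. That value shows no shared shift but cannot tell whether the libraries were prepared as pairs. With the replicate block 9026 genes changed, and the secreted factors passed camera at adjusted p = 0.0362.

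All 716 values of the 48 tested genes selected by the naming rule kept their direction and their side of the threshold in the refits. The requirement of at least a 2-fold change was not among these refits. Under it Piezo1 (1.56-fold lower), Lgals9 (1.68-fold higher) and Aurka (1.95-fold higher), among others, would not be called. Piezo2 had log2 ratios of 1.63 to 3.68 when a library was left out, the lowest a bound against 3 counts, and its adjusted p, where it was tested, ran from 0.047 to 0.22. With a library left out, the lone library of a group is assumed to vary like the other group. Camera with an estimated correlation moved 10 lists past the threshold. They reached adjusted p = 0.168 (interferon, MHC class I, matrix, lysosome, glycolysis) or 0.180 (G2/M, histones, nucleic acid sensing, T and natural killer cell ligands, cell death). Only 2 residual degrees of freedom inform that correlation, and the p-value rests on the same 2. The estimate lay below the preset 0.01 for the matrix (-0.028), lysosome (-0.014), glycolysis (-0.0041), histone, ligand and cell death lists. It lay above 0.01 for the interferon, MHC class I, G2/M and nucleic acid sensing lists. Failure in this form is therefore not by itself a sign of correlation between genes. When a library was left out, the histones ranged from 0.0109 to 0.057 (without irradiated replicate 2), and the secreted factors lay between 0.0370 and 0.0491. The cause of the latter was not tested. Medians that turned sign were those of the channels without a filter (0.43, as more low genes enter) and of the ribosomal proteins with upper quartile scaling (0.0280), library totals (0.0152) and a mean of at least 5 CPM (0.0238). Alternatives planned for a table of normalized values did not apply to counts. Depth limits what can be said of genes such as Piezo2, with 21 counts over the 4 libraries.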

Other observations

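Tests of depth, of exon density and of macrophage markers were chosen after the result had been seen. So were the 7 gene lists of the opening paragraphs, which are not independent evidence of their direction. They hold genes already picked out as most changed, such as Iigp1, C3, Mthfd2 and Etv4. Their camera p-values, adjusted over these 7 lists alone, therefore describe the lists and are not independent support. Interferon-inducible GTPases rose in all 16 tested members, with a median log2 fold change of 6.17, or 5.38 with the 4 genes at 0 in unirradiated cells set to their bounds (camera adjusted p = 7.64e-16, and adjusted p = 0.0504 with an estimated correlation). Gbp4 had 0 counts in both unirradiated libraries and 90 in each irradiated one, and Irgm1 rose with a log2 fold change of 2.10. The annotated span of Gbp4 overlaps those of Gbp8 and Gbp9 on the same strand, so the level of Gbp4 alone is uncertain. Complement and acute phase genes rose in 7 of the 8 tested (median 4.49, camera adjusted p = 2.08e-08, and 0.0504 with an estimated correlation), among them Cp, ceruloplasmin (5.78). The list has 18 genes in the data, and the acute phase genes Saa3, Lcn2, Orm1, Orm2 and Hp were too low to be tested. MHC class II presentation genes rose in 6 of 7 and fell in 1 (median 0.52, adjusted p = 0.0392, and 0.168 with an estimated correlation), led by Cd74 (5.93). The list has 11 genes in the data, and H2-Aa, H2-Eb1, H2-DMb2 and Ciita were too low to be tested. H2-Ab1 was tested on 3 and 0 counts against 33 and 10, and Rfx5 passed although its libraries overlapped. Targets of FOXO transcription factors rose in 18 of 20 (median 0.94, adjusted p = 1.65e-12, and 0.0504 with an estimated correlation). They include Trp53inp1, also in the p53 list, and Bmf and Bcl2l11, also in the cell death list, so these lists are not separate evidence. Txnip, an inhibitor of thioredoxin and of glucose uptake, rose from 165 and 224 to 6894 and 6307 counts, and Klhl24 rose with a log2 fold change of 2.80.

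Ribosome biogenesis genes fell in 26 of 28 tested members and none rose (median -0.81, adjusted p = 7.33e-16, and 0.0504 with an estimated correlation), although ribosomal protein genes went both ways. Fbl, the methyltransferase fibrillarin, fell with a log2 fold change of -1.25, and Ncl, nucleolin, with -0.80. Serine, one-carbon and ATF4 target genes fell in 18 of 22 and rose in 2 (median -0.96, adjusted p = 1.17e-11, and 0.0504 with an estimated correlation). Besides Mthfd2 these included Atf4 itself (-1.20), Asns (-1.57) and Psph (-1.69), while Ddit3 rose (0.67). Targets of the ERK pathway fell in 14 of 18 and none rose (median -0.92, adjusted p = 1.20e-08, and 0.0504 with an estimated correlation). Besides Etv4 these included Etv5 (-1.73), Dusp6, an ERK phosphatase (-1.37), Fosl1 (-1.80) and Ccnd1, cyclin D1 (-1.27), while Dusp4 did not pass (adjusted p = 0.955).

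Near-silent genes, 12366 with a mean under 0.5 CPM, carried 1.90 times as many CPM after irradiation, from 1.18 times in pseudogenes to 2.97 times in protein-coding genes. Depth is argued against, since with every library thinned to 26059171 counts the irradiated group still had 3249.5 more genes detected on average. Reads running over from expressed neighbours are argued against too, since genes over 10 kb from any gene of at least 1 CPM had a ratio of 2.69. Its 95% bootstrap interval was 2.56 to 2.83. The bootstrap intervals here are over genes and leave out the spread between libraries. Reads spread evenly over the genome, as from DNA, are argued against as the whole source: olfactory and vomeronasal receptor genes gained 0.0677 times as many CPM per Mb of exon as other near-silent coding genes (0.0487 to 0.0885), though receptors seen in the table rose too (ratio 2.14) and their close copies could lower the value. Genes silent before irradiation were found in both irradiated libraries 1.78 times as often as chance gives, which lay between the bounds set in advance and decides nothing alone. An effect of irradiation and RNA from another sample stay open, both untested.

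Piezo2 had more counts after irradiation, and a candidate explanation is the same general rise of near-silent genes. Its share of counts in the irradiated libraries, 90.9%, stood at percentile 80.9 among 1953 genes with 15 to 30 counts, whose median share was 65.7%. Because 12.3% of those genes had every count in the irradiated libraries, the measure is saturated, and a change particular to Piezo2 and the general rise cannot be told apart with 21 counts.

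Macrophage and dendritic cell markers rose after irradiation in a culture labelled as a tumour cell line. If such cells had been present, their other abundant transcripts would have risen with Cd74. The other 9 listed markers, leaving out the lysosomal Cd68, gained a median of 0.25% of the CPM that Cd74 gained, and the highest, Lyz2, 4.83%. Cd68 itself gained 201% of that amount, and it is among the markers whose rise is in question. Csf1r, Adgre1 and Itgax had at most 2 counts in any library. This argues against macrophages or dendritic cells as the source. Induction of Cd74 and Cd68 within the irradiated cells may account for the pattern and stays open as a hypothesis that was not tested.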
